A study of Penaeus monodon with 38 samples.

How the data were processed

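The series holds 38 single-colour microarrays of the black tiger shrimp Penaeus monodon. Total RNA came from ovary, eyestalk and cephalothorax of adult females, per the labels' protocols. Wild-caught females were sampled before unilateral eyestalk ablation, at 2 h and at 24 h after it, and later as the ovary passed through a vitellogenic stage, a stage with round cortical rods and a stage with elongated cortical rods. The first 3 of these stages are grouped here as previtellogenic and the last 3 as vitellogenic. For ovary and eyestalk of wild females each stage had 2 arrays, hybridised with pools of 4 and of 5 animals, per the series' design text. Captive-reared females gave 1 pool of 3 animals per stage at 4 stages, so each captive phase had 2 arrays per tissue. Wild cephalothorax had 1 array per stage. Because each array carries a pool, the p-values measure the spread between pools and stages, and the spread between single animals is not measured here.

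RNA was amplified by in vitro transcription, labelled with Cy5 by a non-enzymatic linkage and hybridised alone on each array, per the labels' protocols. The deposited scanner output gives, per spot, the mean and the median foreground intensity on a linear scale, per the file headers. It has no background column and no control spots, and its values reach the scanner's ceiling of 65535. Image software, scanner settings and any step taken by the authors before deposit are not given in the sources used here. The authors' value table was set against the scanner values and holds the same mean intensity. It listed 2239 of the 2240 probes, and all 85082 values (100%) were equal to the scanner value within 0.01, so it is unlogged, uncentred and in the same direction, with nothing left unknown about its scale. Column medians of that table ran from 72.3 to 384.

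Each array has 2240 probes of 34 to 40 bases for 921 target sequences, with at most 5 probes per target. The files pair 244 probes with a gene name through the descriptions of 68 targets, and the other 1996 probes have no gene name here. Names are those of the array's design and can be old. Many named targets come from other crustaceans or insects, and 24 probes come from 5 vertebrate species. Positions given for a probe are base positions in its target sequence. No reference genome was used, so probes have no genomic location here. The table of locus tags was not needed, since names were taken from the files.

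With no background column, the foreground mean was corrected by normexp with an offset of 50, put on the log2 scale and quantile-normalised over the arrays of each fit (limma 3.58.1 in R 4.3.3). Each probe had 1 spot. Probes were tested with limma's lmFit and eBayes, and a probe was called at a Benjamini-Hochberg adjusted p under 0.05 over all 2240 probes. Without any change, about a share of 0.05 of the 2240 probes would have an unadjusted p under 0.05. Unadjusted counts below that share are therefore no sign of change. Ovary and eyestalk were each fitted with 16 arrays and 4 means (origin by phase), so that all 4 groups share one estimate of the spread. The 12 wild arrays of ovary and of eyestalk were also fitted with 6 stage means, the 6 cephalothorax arrays with 2 phase means, and the 30 wild arrays with 3 tissue means. Log2 changes are given with the standard error (SE) of the fit, and group levels as mean log2 normalised intensity with the standard deviation (SD) over arrays. Different probes of a gene were tested one by one, and the text says where they disagree. The mean of the 5 vitellogenin probes and 6 other probe means or single probes were compared between groups by two-sided exact permutation tests, with Benjamini-Hochberg adjustment over the 49 tests made. Some of these probes were chosen on the same arrays, and their low p can lower the adjusted p of the others.

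A non-specific level was set per array as the 90th percentile of the 24 vertebrate-derived probes, a choice made after seeing the data because the arrays hold no control spots. Where no array of a group exceeded it, the change is given as "at least N-fold", computed against the higher of that level and the probe's own value on each array. The share of probes above the level was 30.9% to 48.8% over the ovary arrays, 22.4% to 39% over the eyestalk arrays and 43.5% to 50.3% over the cephalothorax arrays. Of the 24 probes that set the level, 12 were called between wild ovary and eyestalk, beside 1469 of all 2240. Between wild ovary and cephalothorax 8 were called, beside 1259. The level may thus itself differ between tissues, and these shares and the "at least" folds between tissues depend on it. Log2 changes are fitted values, also for probes not above the level in 1 group or in both, and no fold is given for the mean of the vitellogenin probes, since some of these probes are not above it.

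Gene lists were fixed before the data were examined as word patterns on the gene names. Of the 20 lists, 11 matched at least 1 probe and 6 matched at least 5: yolk and lipid handling (11 probes of 3 targets), cortical rod and egg envelope (12 of 3), muscle (13 of 5), eye and neural (97 of 22), digestive gland and proteases (35 of 12), and hormone signalling and ablation-linked enzymes (15 of 3). The histone, ribosomal protein, chaperone, ubiquitin and haemocyte lists had 2 or 3 probes each and are given as counts. No probe name matched the lists for lipid storage droplets, cell cycle, translation factors, mitochondrial respiration, redox and iron, actin and tubulin, haemocyanin, cuticle, or RNA binding, so these are not reported, although the series title names a lipid storage droplet gene. Lists of 5 or more probes were tested with limma's camera at a preset inter-gene correlation of 0.01, adjusted over the lists of a comparison. This preset treats probes of 1 target as nearly independent, so its p-values can be too small. Estimated correlations and fry were the alternatives.

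The rule for named genes, also fixed before the data were examined, takes for each comparison the 10 named probes with the largest positive and the 10 with the largest negative change among those called, 1 per name. Where none was called it takes the 3 with the smallest unadjusted p in each direction. It adds up to 4 members of each list by p. Unnamed probes are limited to 2 IDs per direction by that rule; the few unnamed probes given beyond it, among them all 5 of the eyestalk probes listed by ID and clone Plate-C-C11, were chosen after their values were seen. The text gives the named probes of this rule that carry a comparison and summarises the rest by list.

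Slide, position on the slide and scan series were taken from the labels and tested as batches. There were 10 slides with 2 to 4 arrays each. Every slide held 1 tissue and 1 origin and, in all cases, both phases. The alternatives set before the data were examined were no background correction, scaling of each array to one median, normalisation of all arrays together, a filter on dim probes, the authors' value table, slide as a fixed or random block, the replicate number as a block, array position, matched stages, the compared groups alone, same scan series, the methods' t-test (the design text names t-tests), and each array left out in turn. Added after seeing the data were a filter on probes above the non-specific level on fewer than 2 arrays, the median in place of the mean spot intensity, 2 sets of left-out arrays, the removal of ovary-high probes from the cephalothorax comparison, the removal of vertebrate sequences from the lists, lists by source library, and the fixed lists in further comparisons. No 2 arrays held identical values, and the highest correlation between any pair was 0.994.

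All fits were tested on simulated data with 200 changed probes out of 2240. The spread of each probe was taken from log2 intensities before normalisation, so it includes differences in brightness between arrays. The changed probes were taken from brighter probes only, and the noise was independent between probes and arrays. The shares below therefore do not cover dim probes or slide differences. They can also be lower than the real fits reach, since those use normalised values. For the cephalothorax phases the share is 0%, where the real fit called 260 probes. Of probes changed by 2 log2 units, 64% were recovered for the wild ovary phases, 29% for the wild eyestalk phases, 33% and 38% for captive against wild in the previtellogenic and vitellogenic ovary, 97% for ovary against eyestalk and 80% for ovary against cephalothorax. The corresponding shares were 14% for the captive ovary phases, 10% for the difference of ovary phase effects, 21% for captive against wild eyestalk, 3% for the captive eyestalk phases and 0% for the cephalothorax phases. For the 2 h ovary comparison, both 6-stage tests and the difference of eyestalk phase effects the share was 0%, and it was 3% for the 24 h ovary comparison.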

Results

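Gene expression was measured in ovary, eyestalk and cephalothorax of wild-caught and captive-reared female black tiger shrimp (Penaeus monodon) before and after unilateral eyestalk ablation, the removal of 1 eyestalk that hatcheries use to bring on ovarian maturation. The eyestalk holds a neurosecretory gland whose peptides restrain reproduction. There were 12 wild ovary, 12 wild eyestalk and 6 wild cephalothorax arrays, and 4 captive arrays each of ovary and eyestalk. Median spot intensity ran from 72.3 to 384 over the 38 arrays. The series set out to compare ovarian maturation between wild and captive animals. No probe was named as a lipid storage droplet gene, so that gene is not reported here.

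Wild ovary stood apart from wild eyestalk and cephalothorax first by its cortical rod and egg envelope genes, the extracellular proteins that shrimp oocytes store in peripheral rods and release around the egg. All 12 probes of this list, from 3 targets, were higher in ovary than in eyestalk, with a median log2 difference of 5.59, and all 12 were higher than in cephalothorax, with a median of 3.62. Thrombospondin (probe 1018-1051) was at least 61.5-fold higher in ovary than in eyestalk, ovarian peritrophin 1 (484-517) at least 44.1-fold and ovarian peritrophin 2 (484-518) at least 39.7-fold. Muscle genes ran the other way: 10 of 13 probes were lower in ovary than in eyestalk and 2 were higher, and 12 of 13 were lower than in cephalothorax. Myosin fast heavy chain (161-195) was at least 11.3-fold lower than in eyestalk and at least 7.56-fold lower than in cephalothorax, and myosin alkali light chain (61-95) at least 42.7-fold lower than in cephalothorax. Of 97 eye and neural probes, 57 were lower and 7 higher in ovary than in eyestalk, among them the sinus gland peptides PmSGP-II (312-345, log2 change -3.38 ± 0.26 SE) and hyperglycemic hormone CHH2 (112-145, -2.98 ± 0.32) and arrestin, which ends light signalling in photoreceptors (561-595, at least 5.12-fold lower).

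Further genes separated the tissues. Protein disulfide isomerase, which forms disulfide bonds in secreted proteins, was higher in ovary at all 3 of its probes against both other tissues. Vitellogenin, the yolk protein precursor, was at least 3.28-fold higher in ovary than in eyestalk at probe 7005-7039. Phenylalanine/tryptophan hydroxylase (223-257) was 9.24-fold lower in ovary than in eyestalk. Cathepsin L (566-599), a lysosomal protease, was at least 8.66-fold lower in ovary than in cephalothorax, and haemocyte transglutaminase (337-371), the clotting enzyme of the blood, at least 3.1-fold lower. The digestive gland and protease list had 10 probes higher and 8 lower than in cephalothorax. Against eyestalk, histone H1 was higher in ovary at 1 of 2 probes, ribosomal protein probes were lower at 2 of 3, and ubiquitin passed at 0 of 2. By limma at adjusted p under 0.05, 1469 probes differed between ovary and eyestalk (641 higher, 828 lower) and 1259 between ovary and cephalothorax (726 higher, 533 lower). By camera the cortical rod list was higher against eyestalk (adjusted p = 1.57e-09; adjusted p = 0.141 with an estimated correlation) and against cephalothorax (4.6e-06; adjusted p = 0.234 with an estimated correlation). Muscle genes were lower against both tissues (adjusted p = 0.0172 and 4.6e-06; adjusted p = 0.53 and 0.234 with an estimated correlation), and eye and neural genes against eyestalk (0.000141; adjusted p = 0.223 with an estimated correlation). Each slide held 1 tissue, and with slide as a random block the counts were 1332 and 1124.

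In wild ovary, vitellogenin rose as oocytes entered vitellogenesis. The mean of its 5 probes was 10.42 ± 0.46 on the log2 scale in the vitellogenic arrays and 8.32 ± 0.95 in the previtellogenic arrays (SD, n = 6 and 6), a difference of 2.11. The exact permutation p was 0.00216, the smallest that 924 splits can give, and 0.0265 adjusted over 49 tests. The other tests with that same p were of probes chosen after their phase values were seen, which lowers the adjusted value. No pass is therefore claimed from it. Within the 3 slides the difference was 1.92, 1.84 and 1.08. The single probes differed in size: 7005-7039 had a log2 change of 2.91 ± 0.61 SE, 7245-7279 of 2.61 ± 0.50, 6949-6983 of 1.87 ± 0.44 and 7311-7345 of 0.65 ± 0.24, and 7519-7553 was 5.67-fold higher. The unnamed clone Plate-C-C11 (52-87, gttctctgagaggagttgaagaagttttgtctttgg) moved in the same arrays, with a log2 change of 1.46 ± 0.26.

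**Figure D1:**
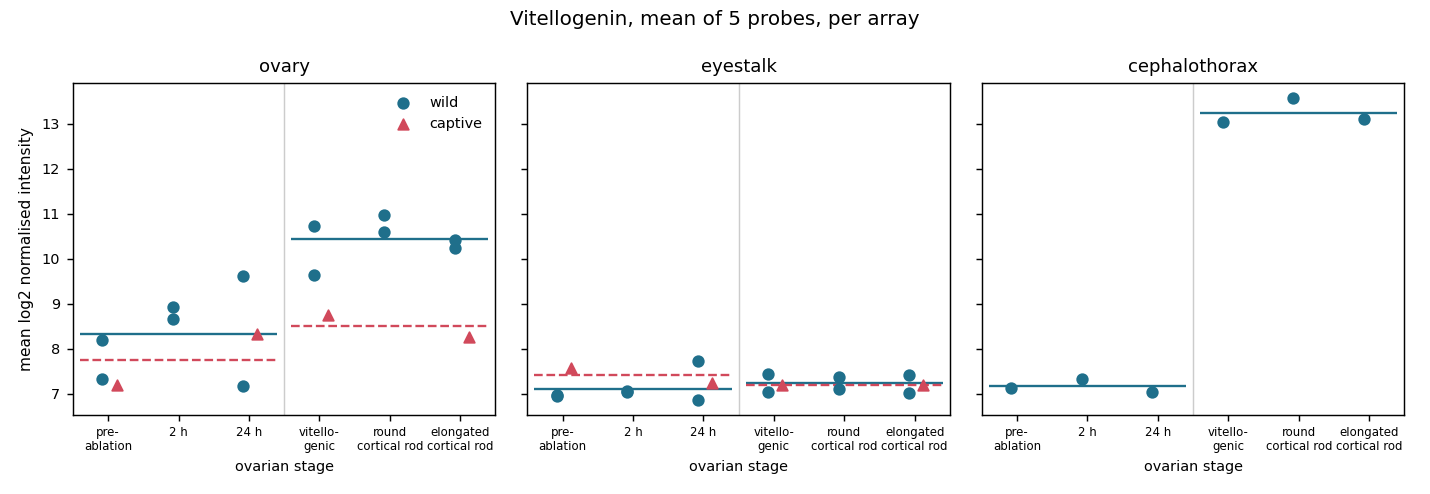
Mean log2 normalised intensity of 5 vitellogenin probes on each array, by ovarian stage, in ovary, eyestalk and cephalothorax; circles are wild arrays, triangles are captive arrays (the captive post-ablation previtellogenic array is drawn at 24 h), and lines are phase means (solid wild, dashed captive). Wild means are 8.32 and 10.42 in the previtellogenic and vitellogenic ovary and 7.16 and 13.23 in the cephalothorax, and the captive vitellogenic ovary lies at 8.51.

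Yolk and lipid handling was the list that moved with the wild ovary phase: 5 of its 11 probes, all vitellogenin, passed when adjusted over the list alone, and 0 over all probes. Its other members, phospholipase C and a fruit fly vitellogenin receptor, did not pass. Camera gave an adjusted p of 6.12e-09 for the list, and adjusted p = 0.0059 with an estimated correlation. Cortical rod and egg envelope genes stood at 13.65 ± 0.17 in the previtellogenic and 13.62 ± 0.21 in the vitellogenic arrays (SD, n = 6 and 6; exact permutation p = 0.835). Named probes outside vitellogenin included ovarian peritrophin 2 (644-678, log2 change -0.45), protein disulfide isomerase (225-259, -0.42) and ovarian peritrophin 1 (8-41, 0.38), all with adjusted p = 0.976. Muscle, eye and neural, protease and hormone signalling lists did not pass by camera (adjusted p from 0.261 to 0.853). No single probe passed limma's adjusted p over all 2240 probes (smallest 0.0983), where 59 had an unadjusted p under 0.05 and the methods' t-test called 0 (75 unadjusted). Without the wild 24 h replicate 2 array 5 probes passed, and 3 passed when probes near the non-specific level were left out, including vitellogenin 7245-7279 and 7519-7553 (both adjusted p = 0.0337).

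The hours after ablation left no probe past the threshold in wild ovary. At 2 h against preablation the named probes included a cathepsin L precursor (57-91, log2 change 0.59 ± 0.25 SE) and arginine kinase (305-339, -0.62 ± 0.39), the phosphagen enzyme of invertebrate muscle. At 24 h they included arginine kinase (5-39, 0.57 ± 0.28) and protein disulfide isomerase (225-259, -0.41 ± 0.28). Limma called 0 probes at 2 h (43 with unadjusted p under 0.05), 0 at 24 h (4) and 0 over the 6 stages (22), and no other tool was run on these. These unadjusted counts are each below a share of 0.05 of all probes. Without the wild ovary 2 h replicate 2 array the 2 h count was 45, and each stage had 2 arrays.

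In captive ovary, the probes that rose from the previtellogenic to the vitellogenic phase included 2 for ovarian peritrophin 1, with log2 changes of 1.98 ± 0.41 SE (8-41) and 1.19 ± 0.28 (484-517). Arrestin (145-179) rose by 1.23, hyperglycemic hormone CHH2 (370-404) by 1.01, farnesoic acid O-methyltransferase (1708-1742), which makes the crustacean hormone methyl farnesoate, by 0.73 and cathepsin D (417-451) by 0.67. Mandibular organ inhibiting hormone (883-917) fell by 1.63, phospholipase C (101-135) by 0.98, the 5-HT1 receptor (1516-1550) by 0.92, pigment dispersing hormone PDH 2 (78-112) by 0.85, cathepsin C (1593-1627) by 0.79 and a moult-inhibiting hormone-like peptide (425-459) by 0.79. Vitellogenin 7245-7279 had a log2 change of 2.02 that did not pass (adjusted p = 0.144), and the mean of its 5 probes was 8.51 ± 0.35 against 7.75 ± 0.80 (SD, n = 2 and 2; exact permutation p = 0.667, smallest possible 0.333).

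Probes of one gene disagreed in captive ovary. PmSGP-V rose by 0.94 at probe 9-43 and fell by 1.34 at 272-305, and the retinoid X receptor rose by 0.83 at 101-135 and fell by 0.87 at 162-199. Fish-derived probes for cathepsin S (641-675) and a zona pellucida protein (4931-4964) fell by 1.24 and 0.83, and farnesoic acid O-methyltransferase, CHH2 and cathepsin D were not above the non-specific level on any captive array. By list, 2 of 12 cortical rod probes rose (4 adjusted over the list alone), 4 of 97 eye and neural probes rose and 4 fell, 1 of 35 protease probes rose and 3 fell, and 2 of 15 hormone signalling probes rose and 1 fell. No list passed by camera (adjusted p from 0.124 to 0.873). In all, limma called 212 probes, 62 higher and 150 lower. Never above the non-specific level were 54 of them (25.5%, against 34.3% of all probes), and 4 of the 24 vertebrate-derived probes were called. The preablation array, 1 of the 2 previtellogenic ones, had 30.9% of probes above that level. The other 3 captive ovary arrays had 43.9% to 46.4%, so the calls may rest in part on that array. With each array scaled to one median the count was 73, with 58 higher and 15 lower, so the balance of directions turned with the scaling. The methods' t-test called 0 (261 unadjusted), as did a fit of the 4 captive arrays alone, and without the captive elongated cortical rod array 36 were called.

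The ovarian phase effect differed between captive and wild animals at 48 probes, 14 with a higher and 34 with a lower change in captive animals. Farnesoic acid O-methyltransferase (1708-1742) differed by 0.80 ± 0.18 SE on the log2 scale (adjusted p = 0.0401). The fish-derived cathepsin S probes 641-675 and 753-786 differed by -1.31 and -1.09. Of 16 ovary arrays, these 3 probes were above the non-specific level on 0, 2 and 1, and 0 of the 48 passed when probes near that level were left out. Vitellogenin 7519-7553 had a difference of -1.87 that did not pass (adjusted p = 0.301). Median scaling and the use of matched stages each left 0 probes by limma. Unadjusted p was under 0.05 at 297 and 417 probes in these settings, against 437 in the comparison as fitted. Without the captive elongated cortical rod array 1 probe was called, which was not among the 48, and without the captive post-ablation previtellogenic array there were 256.

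Before vitellogenesis, captive ovary differed from wild ovary at single probes of neuropeptide, protease, secretory and egg envelope genes, and none of the 6 gene lists fixed by name passed as a whole. Pigment dispersing hormone PDH 1 (290-328) was higher in captive ovary by 3.11 ± 0.52 SE on the log2 scale, PDH 3 (250-284) by 2.81 ± 0.49, PmSGP-II (312-345) by 2.52 ± 0.48, PmSGP-IV (313-346) by 1.94 ± 0.38 and mandibular organ inhibiting hormone (883-917) by 1.70 ± 0.39. Myosin fast heavy chain (29-63) was higher by 1.33, cathepsin L (525-559) by 1.33 and cathepsin C (1593-1627) by 1.14. Protein disulfide isomerase was lower at 314-348 (-1.98 ± 0.41) and 225-259 (-0.84), ovarian peritrophin 1 (8-41) at -1.76 ± 0.33 and histone H1 (52-85) at -1.40 ± 0.44. Smaller decreases were fitted for CHH2 (370-404, -0.88), the Pem-SGP-C1 precursor (516-550, -0.81), PDH 2 (9-43, -0.66), a subunit of NADH:ubiquinone oxidoreductase (17-51, -0.65), the receptor E75 (3261-3295, -0.64) and the vitellogenin receptor (329-363, -0.51). Of these 6 probes, the NADH:ubiquinone oxidoreductase probe alone was above the non-specific level on any array of the 2 groups.

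These neuropeptide calls rested on 1 probe or a few of each gene. The other 4 probes of PDH 1 and of PDH 3 did not pass, PDH 2 was higher at 78-112 (0.75) and lower at 9-43, and PmSGP-V was higher at 272-305 (1.41) and lower at 9-43 (-0.79). Among the 24 vertebrate-derived probes that set the non-specific level 7 passed, beside 504 of all 2240 probes, so part of the calls may be non-specific. They include a cathepsin S and an SF-1 probe of fish origin, at 1.22 (641-675) and -0.64 (1366-1400). By list, 21 of 97 eye and neural probes were higher and 7 lower, 8 of 35 protease probes higher and 3 lower, 2 of 3 protein disulfide isomerase probes lower, and 1 of 12 cortical rod probes lower. No list passed by camera (adjusted p from 0.456 to 0.595). Limma called 504 probes, 302 higher and 202 lower, and 467 with slide as a random block. Under median scaling the split was 116 higher and 135 lower of 251. Never above the non-specific level were 177 of the 504 (35.1%), near the 34.3% over all probes. On the captive preablation array 30.9% of probes were above that level, against 43.9% to 46.4% on the other 3 captive ovary arrays; without that array and without probes near the level 37 were called.

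In the vitellogenic phase, vitellogenin signal was lower on the 2 captive ovary arrays than on the wild ones, but neither its 5-probe mean nor any single probe passed after adjustment. The mean was 8.51 ± 0.35 against 10.42 ± 0.46 (SD, n = 2 and 6), a difference of -1.92 with both captive arrays below all 6 wild arrays. The exact permutation p was 0.0357, the smallest that 28 splits can give, and 0.194 adjusted over 49 tests. All 5 probes were lower, from -3.02 ± 0.86 SE (7005-7039) to -1.26 ± 0.35 (7311-7345), with limma adjusted p from 0.126 to 0.304. Clone Plate-C-C11 (52-87) was lower by the same measure, at -1.93 (exact permutation p = 0.0357), and so was the mean of the 13 muscle probes, at 8.92 ± 0.05 against 9.23 ± 0.10 (SD, n = 2 and 6; exact permutation p = 0.0357, 0.194 adjusted). Arginine kinase (169-203, -2.03, adjusted p = 0.0605) and protein disulfide isomerase (153-187, -1.47, adjusted p = 0.0959) were also below wild ovary and missed the threshold. Yolk and lipid handling was lower by camera (adjusted p = 0.00623; adjusted p = 0.234 with an estimated correlation), with 4 probes past the list alone, and the cortical rod list was not (adjusted p = 0.396). Limma called 1 probe, clone Plate-C-A3 (137-171, 0.68), which was never above the non-specific level, and 346 had an unadjusted p under 0.05. The 2 captive vitellogenic arrays share 1 slide that holds no wild array.

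In wild eyestalk, 14 probes of 8 unnamed targets fell as the ovary became vitellogenic, and none rose. Their median log2 change was -3.52. Clone F-D12 (57-91, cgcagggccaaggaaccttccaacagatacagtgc) went from 13.05 ± 1.34 to 7.97 ± 0.92 (SD, n = 6 and 6), a change of -5.08 ± 0.65 SE or 33.8-fold (adjusted p = 0.00153). Contig[0332] (45-79) was at least 18.3-fold lower and clone Plate-B-D2 (113-147, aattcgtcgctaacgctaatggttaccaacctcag) at least 5.24-fold lower (adjusted p = 3.22e-05). Others of the 14 include Contig[0314] (73-107, -3.83) and Contig[0331] (57-91, -2.85). In ovary 9 of the 14 were not above the non-specific level on any array, and F-D12 (57-91) was above it on all 16.

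**Figure D2:**
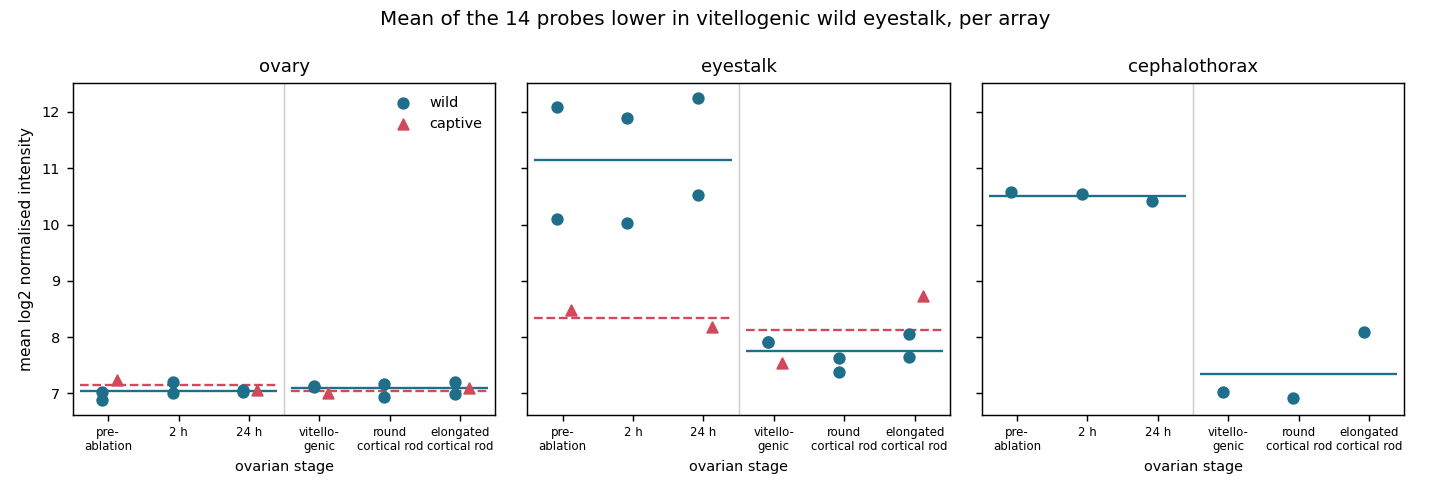
Mean log2 normalised intensity of the 14 probes called lower in vitellogenic wild eyestalk on each array, by ovarian stage and tissue; circles are wild arrays, triangles captive arrays (post-ablation previtellogenic drawn at 24 h), and lines are phase means (solid wild, dashed captive). The probes were chosen on the wild eyestalk arrays, where the means are 11.14 and 7.75; in cephalothorax they are 10.51 and 7.34.

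No named eyestalk gene passed between the wild phases. PDH 2 (78-112, log2 change -0.43), PmSGP-IV (33-67, -0.60) and the serotonin receptor (3249-3283, -0.54) had the smallest p among lower named probes, and ovarian peritrophin 1 (664-697, 0.86) and farnesoic acid O-methyltransferase (1418-1452, 0.54) among higher ones, with adjusted p from 0.272 to 0.515. Arrestin (4-37) had a change of -2.01 and arginine kinase (169-203) of -1.48, with previtellogenic SDs of 2.20 and 1.80. By camera, eye and neural genes (38 probes above 0 and 59 below) and muscle genes (3 above, 10 below) shifted down and cortical rod genes (11 above, 1 below) shifted up, with adjusted p of 0.00911, 0.0162 and 0.0274. With an estimated correlation all 3 had adjusted p = 0.554, and 0 members passed alone. The muscle mean was 11.3, 11.5 and 11 on the 2 h replicate 1, preablation replicate 2 and 2 h replicate 2 arrays, and 8.74 to 9.55 on the other 3 previtellogenic arrays. Limma called 12 probes with slide as a block (10 of the 14 among them) and the methods' t-test 6. Within the 3 slides the mean of the 14 probes differed by -4.16, -2.23 and -2.87.

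Captive eyestalk showed no called probe between phases. The named probes with the smallest p included farnesoic acid O-methyltransferase (1708-1742, log2 change 0.43; 1418-1452, -0.96), the Pem-SGP-C2 gene (573-607, 0.78) and arginine kinase (361-395, -1.17), all with adjusted p = 0.548. The 14 probes of wild eyestalk had a median change of 0.42 in captive eyestalk, with 5 below 0, from a previtellogenic mean of 8.33 ± 0.21 against 11.14 ± 1.04 in the wild arrays on which they were chosen (SD, n = 2 and 6). Of these, Contig[0331] had captive changes of -2.28 (57-91) and -3.54 (33-67), beside -2.85 and -3.44 in wild eyestalk, and for 1 probe of another contig the captive and wild changes differed by -0.09. Over all probes the change of 1 differed between origins, that of clone Plate-B-D2 (113-147, difference 4.35 ± 0.68 SE, adjusted p = 0.0429). Limma called 0 probes between the captive phases (191 unadjusted), as did the methods' t-test (194 unadjusted). The interaction call was lost under median scaling, matched stages and no background correction.

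Captive and wild eyestalk differed at 12 probes over both phases, 7 higher and 5 lower in captive animals. The named ones were vitellogenesis inhibiting hormone of a lobster (53-87, log2 difference 0.44 ± 0.08 SE) and a cathepsin B-like protease (439-473, 0.43 ± 0.09), neither above the non-specific level on any eyestalk array. In all, 9 of the 12 were never above that level on the 16 eyestalk arrays. The others were clone Plate-C-B5 (289-323), higher by 1.40 ± 0.26, and clones plateB-H1 (307-341) and plateC-A1 (45-79), lower at -2.22 ± 0.44 and -1.96 ± 0.40. With slide as a random block, under median scaling and with matched stages the count was 0. Limma's unadjusted p was under 0.05 at 173, 411 and 329 probes in these settings, against 430 in the comparison as fitted. Over the 6 wild eyestalk stages limma called 0 probes (38 unadjusted, below a share of 0.05 of all probes).

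Cephalothorax, which houses the digestive gland, muscle and part of the ovary, showed the steepest rise of vitellogenin. The 5-probe mean went from 7.16 ± 0.14 to 13.23 ± 0.29 (SD, n = 3 and 3), a difference of 6.07 on the log2 scale, with differences of 5.98 and 6.25 within the 2 slides. Probes 7005-7039 and 6949-6983 rose at least 163-fold and 62.8-fold, and 7519-7553 and 7245-7279 by 6.15 ± 0.24 SE and 6.96 ± 0.40 on the log2 scale (adjusted p from 6.28e-05 to 0.00111). Clone Plate-C-C11 (52-87) rose at least 41.6-fold (adjusted p = 0.00554). The 40S ribosomal small subunit protein (89-123) rose by 1.94, phenylalanine/tryptophan hydroxylase (223-257) by 1.36, arginine kinase (305-339) by 1.36, muscle LIM protein (73-106) by 1.33, ubiquitin (283-317) by 1.21, haemocyte transglutaminase (193-227) by 1.09 and ribosomal protein L18 (57-91) by 0.96.

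Egg envelope genes fell in the same cephalothorax arrays. Ovarian peritrophin 2 (484-518) fell by 3.39, thrombospondin (1018-1051) by 3.37 and ovarian peritrophin 1 (664-697) by 2.83. All 12 probes of the cortical rod list were below 0, with a median of -2.17; 4 passed over all probes and 11 adjusted over the list alone. The fixed lists were tested here as an addition made after seeing the data, and camera gave adjusted p = 1.37e-08 for this list and 0.000917 for yolk and lipid handling, where 5 probes rose, both with adjusted p = 0.145 with an estimated correlation. Muscle (adjusted p = 0.0896), eye and neural, protease and hormone signalling lists did not pass (the last 3 from 0.815 to 0.925). Probes for ovarian transcripts moved with the egg envelope genes: of 233 probes over 2 log2 units higher in wild ovary than in eyestalk, 94.8% were lower in the vitellogenic cephalothorax, with a median of -1.58 (quartiles -2.47 and -0.86).

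**Figure D3:**
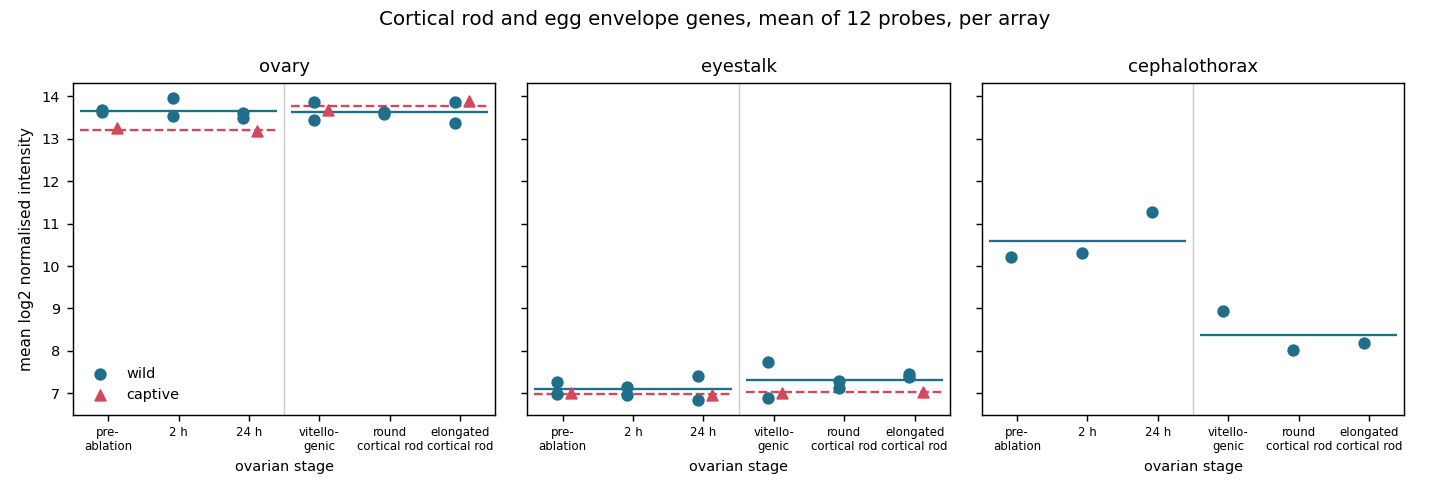
Mean log2 normalised intensity of 12 cortical rod and egg envelope probes on each array, by ovarian stage and tissue; circles are wild arrays, triangles captive arrays (post-ablation previtellogenic drawn at 24 h), and lines are phase means (solid wild, dashed captive). Wild ovary stands at 13.65 and 13.62 in the 2 phases and cephalothorax at 10.6 and 8.38.

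Limma called 260 cephalothorax probes, 123 higher and 137 lower, from 185 targets. With slide as a block there were 207, and under median scaling 168, of which 55 were higher and 113 lower. The methods' t-test called 18, and exact tests of 3 against 3 arrays cannot give a p below 0.1. Leaving out 1 array gave between 98 (without elongated cortical rod) and 373 (without 24 h). Of the 14 probes that fell in wild eyestalk, all 14 were below 0 in cephalothorax, with a median of -3.14, and 10 were among its lower calls, where independent lists of these sizes would share 0.856.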

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

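The tests in this part were chosen after the results were seen, apart from the comparisons of captive with wild animals and of their phase effects and the fits with median scaling or with slide as a block, which were set before. In 80 sets of values from 6 arrays each, 3 single arrays lay further from the rest than a gap test allows, and chance gives about 1 in 20. The wild eyestalk 24 h replicate 2 array had a vitellogenin mean of 7.72 with the nearest previtellogenic array at 7.05 (gap over range 0.785). The wild eyestalk round cortical rod replicate 1 array had 34.5% of probes above the non-specific level with the nearest vitellogenic array at 29.5% (0.667). The wild ovary vitellogenic replicate 1 array had vitellogenin 7005-7039 at 10.3 with the nearest vitellogenic array at 11.8 (0.654). The phase effect differed between captive and wild animals at 48 probes in ovary and at 1 probe in eyestalk, and under median scaling at 0 in both (limma). Unadjusted p was under 0.05 at 437 and 142 probes before that scaling and at 297 and 71 under it.

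Regrouping the arrays at random tells how often other groups of the same sizes give as many calls. For the wild ovary phases, with 0 calls, every one of the 100 gives as many by construction (highest other 41), so they decide nothing there. For wild eyestalk phases 3 of 100 gave 14 or more, the real one included, and the highest other gave 82. For captive against wild eyestalk 2 of 100 gave 12 or more, and the highest other gave 81. Both shares are under 0.05, but chance is left open for both comparisons, since the regroupings mix slides. For the wild phases 3 of 100, drawn from 462 possible, is also too close to that limit to exclude chance. For captive against wild, the 4 captive arrays share a slide with no wild array. There 0 probes passed with slide as a random block (limma, 173 unadjusted with the block and 430 without it). Regroupings that call several times the real number point to a structure of the eyestalk arrays other than phase and origin. For ovary against eyestalk and against cephalothorax 1 of 100, the real one, gave 1469 and 1259 calls, the highest others being 588 and 961. For the cephalothorax phases the real split gave 260 and the highest other 0, and 10 splits are too few for a share under 0.05.

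The difference between captive and wild ovary before vitellogenesis was weighed against 3 technical explanations. A single dim array is argued against as the whole cause: over the 462 probes called with the captive preablation array alone, the other captive previtellogenic array was shifted the same way by a median of 0.42, where single wild arrays lay between -0.0897 and 0.142. Signal near the non-specific level leaves 175 calls among 1271 brighter probes, though 7 of the 24 vertebrate-derived probes that set that level were called as well. A difference of the captive slide would also act on the vitellogenic arrays of that slide, where 1 probe was called and 346 had an unadjusted p under 0.05 (limma). Simulated changes of 1 and 2 log2 units were recovered there at 6% and 38%, shares that can be too low because of the simulated spread. How large a slide difference would go uncalled is thus not known, and the count of 1 cannot exclude one. The shift of 0.42 was also measured on that slide. The first 2 acting together stay open for most of the calls, since 37 probes were called without the array and the dim probes, 25 of them among the 504. Origin, season and handling of the animals may also differ between the groups and were not tested.

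The cephalothorax pattern joins a fall of ovarian transcripts with a rise of vitellogenin. Ovarian tissue in the previtellogenic cephalothorax samples is a candidate explanation for the fall, since 94.8% of 233 ovary-high probes were lower in the vitellogenic arrays, as a smaller share of ovary would give. A difference between the 2 slides is argued against by medians of -1.60 and -1.55 over these probes within the slides, each of which held as many arrays of both phases. Ovarian tissue in the vitellogenic samples is argued against as the source of the vitellogenin rise by the median of -2.17 of the cortical rod probes, which are bright in ovary at every stage. Synthesis of vitellogenin in another cephalothorax tissue, such as the digestive gland, may account for that rise; with 3 arrays a phase and no dissected digestive gland it remains a hypothesis.

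The 14 probes that fell in wild eyestalk were weighed against muscle content, slides and integument. Their median was -3.98 without the 3 muscle-rich previtellogenic arrays and -3.22 with slide as a block. The 14 were chosen on these same arrays, so both medians are tilted towards a phase change and cannot decide on muscle, slide or scan series. A new fit without the 3 arrays called 10 probes, 8 of them among the 14. With slide as a block 12 were called, 10 of them among the 14. Whether the 14 are transcripts of the integument cannot be told apart with these data: the 3 exoskeletal protein probes had a median of 1.59 in cephalothorax and none passed. A change linked to the moult cycle or to time after ablation may underlie the fall in both tissues, and stage and time since ablation run together in this design.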

How the results depend on the processing

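Alternatives that leave out dim probes by the non-specific level, use the median spot intensity, leave out 3 muscle-rich arrays, leave out the captive preablation array with dim probes, leave out ovary-high probes, or leave vertebrate sequences out of the gene lists were added after seeing the data; the others were set before. Of the counts under alternatives other than left-out arrays, 116 stayed within 1.5 times the value reported and 46 did not. For the single probes given in the text, named or unnamed, 1133 values kept direction and side of the threshold, 197 kept direction and missed it, 4 kept direction and passed it, and 1 turned: arginine kinase 169-203 in wild eyestalk, 0.11 without the 3 muscle-rich arrays. Counts below are probes past adjusted p under 0.05, limma unless named.

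Median scaling gave 73 (captive ovary phases), 0 (difference of ovary phase effects), 251 (captive against wild previtellogenic ovary), 3 (vitellogenic ovary), 0 (captive against wild eyestalk), 0 (difference of eyestalk phase effects) and 168 (cephalothorax). Under it the median of all probes was 0.177, 0.142 and -0.208 for the first 3, -0.131 for the eyestalk difference and 0.128 for ovary against cephalothorax, and within 0.1 of 0 for the other comparisons of 2 groups. No background correction gave 0 for vitellogenic ovary and 0 for the eyestalk difference, and normalising all 38 arrays together gave 0 for vitellogenic ovary. Leaving out dim probes gave 99, 16, 276, 0 and 1 for captive ovary phases, the ovary difference, captive against wild previtellogenic and vitellogenic ovary, and captive against wild eyestalk. The non-specific level as the limit gave 42, 0, 175, 0 and 0 for the same, and 3 for wild ovary and 26 for wild eyestalk phases. With the captive preablation array also left out there were 33, 16 and 37 for captive ovary phases, the ovary difference and captive against wild previtellogenic ovary. Fewer probes were tested in the dim-probe settings, which alone does not account for the falls. For captive against wild previtellogenic ovary 504 of 2240 became 175 of 1271 with the non-specific level as the limit. That limit raised the counts for wild eyestalk (14 to 26) and cephalothorax phases (260 to 324).

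Only the groups compared in the fit gave 0 for captive ovary phases, 207 and 0 for captive against wild previtellogenic and vitellogenic ovary. Matched stages gave 0 for the ovary difference, vitellogenic ovary, captive against wild eyestalk and the eyestalk difference. The methods' t-test gave 0 for captive ovary phases, 6 for wild eyestalk and 18 for cephalothorax. Slide as a random block gave 0 and the same scan series 4 for captive against wild eyestalk, and the median spot intensity gave 21. Array position as a block gave 7 for wild eyestalk. The replicate number as a block gave 1 for wild ovary (vitellogenin 7519-7553, adjusted p = 0.0201), 23 for wild eyestalk and 2 across eyestalk stages. In wild ovary it raised the probes with unadjusted p under 0.05 from 59 to 160. The replicate 1 minus replicate 2 difference of each stage was correlated between stages, over 15 stage pairs. The median was 0.176 in ovary (lowest -0.319, 10 over 0.1) and 0.371 in eyestalk (lowest -0.133, 12 over 0.1). Since not every pair was over 0.1 the numbers were not taken to pair the arrays, but most pairs were, so a shared effect of the number stays open. Without the 3 muscle-rich arrays the eyestalk difference gave 3, and without ovary-high probes cephalothorax gave 99. Of 30 list tests 5 passed with camera, 1 with estimated correlations and 2 with fry.

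Leaving out 1 array at a time gave 0 to 5 for wild ovary phases, 36 to 396 for captive ovary phases, 1 to 256 for the ovary difference, 276 to 573 and 0 to 5 for captive against wild previtellogenic and vitellogenic ovary, 0 to 3 over ovary stages, 0 to 45 at 2 h, 0 to 3 at 24 h, 10 to 19 for wild eyestalk, 0 to 3 for captive eyestalk, 0 to 92 for captive against wild eyestalk, 0 to 3 for the eyestalk difference, 0 to 1 over eyestalk stages, 98 to 373 for cephalothorax, 1439 to 1491 for ovary against eyestalk and 1175 to 1247 for ovary against cephalothorax. Where this leaves a group with 1 array, that array is assumed to vary like the other groups. The cause of these differences in count was not tested. The share of probes over the non-specific level ran lowest in eyestalk, at 22.4% to 39%, though that level may itself differ between tissues.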

Other observations

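All tests in this part were chosen after the results were seen. Probes from an ovarian library and from a hepatopancreas library (the digestive gland of shrimp) differed in direction in the vitellogenic cephalothorax, and probes from an eyestalk library went with the latter. Of 345 ovarian library probes 15 were higher and 77 lower (camera adjusted p = 1.28e-10; adjusted p = 0.036 with an estimated correlation), and of 351 hepatopancreas library probes 38 were higher and 4 lower (1.42e-05; adjusted p = 0.036 with an estimated correlation). Of 130 eyestalk library probes 10 were higher and 0 lower (0.0182; adjusted p = 0.172 with an estimated correlation). In ovary against cephalothorax the ovarian library had 237 probes higher and 24 lower, and the hepatopancreas library 49 higher and 193 lower. The median correlation with wild ovary arrays was 0.541, 0.558 and 0.621 for the preablation, 2 h and 24 h cephalothorax arrays, and 0.391, 0.343 and 0.331 for the vitellogenic, round and elongated cortical rod arrays.

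Phase effects over 1369 probes correlated between wild eyestalk and cephalothorax (Pearson 0.38, Spearman 0.279), between captive eyestalk and cephalothorax (0.252 and 0.378) and between wild and captive eyestalk (0.143 and 0.186), so the closer match to cephalothorax turns with the measure. In captive against wild previtellogenic ovary, 34 ovarian library probes were lower and 9 higher (camera adjusted p = 5.49e-05; adjusted p = 0.238 with an estimated correlation).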
